A study of Mus musculus with 17 samples.

How the data were processed

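The data are single-nucleus RNA sequencing of mouse cerebral cortex (C57Bl6). Per the labels, a paper strip soaked in 10% FeCl3 lay on the left distal middle cerebral artery for 5 minutes to occlude it, and cortex was taken 3, 7, 14 or 28 days later or after sham surgery. There were 17 libraries in 5 groups: 3 sham, 3 at day 3, 4 at day 7, 3 at day 14 and 4 at day 28. The labels do not say that each library came from a separate animal, so p-values measure the spread between libraries. Per the labels, nuclei were isolated from frozen tissue with Triton X-100, and libraries were made with the Chromium Next GEM 3' kit version 3.1 and sequenced on a NovaSeq.

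Per the labels, the authors mapped reads with Cell Ranger 4.0 to the mouse mm10 pre-mRNA reference, which counts intron reads, and joined the libraries with cellranger aggr, which subsamples them to equal confidently mapped reads. Seurat 3.2.2 is named in the processing notes. The deposited matrix holds the authors' normalized expression as a natural logarithm, ln(1 + 10000 x UMI count / total UMI count of the nucleus), and lists no zeros. The deposited table of nuclei gives each nucleus its library, its total UMI count and its number of detected genes, as counts. The filters on nuclei and genes are not given in these sources.

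Inverting the formula returned a whole UMI count for 100.0% of the 151523745 entries within a tolerance of 1e-06. The recovered counts summed to the deposited total in each of the 107020 nuclei. The matrix holds 20785 gene symbols and 303982882 UMIs. Over libraries the median UMIs per nucleus ranged from 1646.5 to 2499. The UMIs are counts of molecules, and intervals and floors cover counting error only. Gene coordinates and lengths came from the GENCODE annotation of GRCm38, matched by symbol, and the build is the one the labels name. Between 98.4% and 99.3% of the tested genes of each class had a match.

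The deposited table holds no cell types, so nuclei were grouped anew. After scaling (values clipped at 10), 2000 variable genes gave 30 principal components, a graph of 20 nearest neighbours and 42 Leiden clusters (resolution 1.5, seed 1; leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Clusters were named from 149 fixed marker genes, of which 142 were measured. A name needed at least 100 nuclei, at least 3 detected markers (at least 10 CPM and over 2-fold above the median cluster) and a mean log2 score of at least 0.5. A cluster stayed unnamed where a second class scored at least 1.3 and over 0.6 of the best score (related oligodendrocyte classes and striatal with inhibitory neurons aside), where 3 or more mitochondrial genes stood among its 10 top genes by fold, where markers of another class outnumbered its own among these, or where none of its own markers stood among these and its depth was low or a second score reached 0.8 of the best. Clusters that joined several classes were split again at resolution 0.6, with at least 30 nuclei per part. This named 28 of 42 clusters whole. Unnamed nuclei made up 20.1% (21512). Class names are written with "-like", since no protein or position was measured. Doublets were not called, and mixed clusters were left unnamed.

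The partition is sensitive to last-digit differences in arithmetic, so processor settings were fixed. A first partition under other settings differed, and the added alternatives and the tests chosen once results had been seen were chosen on it. The rule on close scores was added after a cluster of 757 nuclei with neuronal markers scored 1.28 as OPC-like against 1.26 as excitatory neuron-like. That rule was set on marker scores before any test on the final partition was seen. A second seed gave 45 clusters and left 93.3% of nuclei with the same name, at least 94.1% in each tested class and 71.1% among unnamed nuclei.

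UMIs were summed per library over all nuclei (whole cortex) and per library and class where at least 20 nuclei were present. Sums were normalized with TMM and fitted in 1 edgeR quasi-likelihood model over the 5 groups (estimateDisp, glmQLFit; edgeR 4.0.16, limma 3.58.1, R 4.3.3) after filterByExpr. Each day was compared with sham, all 4 days together with sham, and day 28 with day 3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, adjusted per class and comparison, and adjusted p-values below are from these fits unless another tool is named. Values per group are the mean CPM (UMIs scaled to a fixed library total) over libraries ± SD, and log2 folds are edgeR estimates ± SE. Where the 3 sham libraries held 0 UMIs of a gene, the fold of UMIs summed over libraries is a lower bound against 3 counts over the sham group. Where they held 1 to 3 UMIs, the ratio of summed counts is given with its exact 95% counting interval. Shares of nuclei were tested with edgeR quasi-likelihood on nuclei counts with the library's total as offset, adjusted over classes and comparisons. A permutation test of the F statistic over the 5 groups (100000 draws) stands beside it. Exact tests cannot go below 0.1 for 3 against 3 libraries (0.0571 for 4).

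The 23 gene lists were tested with camera on voom values (preset correlation 0.01, at least 3 measured members), with adjustment over the 255 tests in classes and the 115 in whole cortex. The lists are those named for whole cortex at day 3. Named genes follow a rule. Per class and day they are the 3 largest rises and 3 largest falls (5 and 5 in whole cortex) among genes past the threshold with a mean of at least 10 CPM and every library of the day on 1 side of every sham library. Predicted genes named Gm or Rik, mitochondrial genes and markers of other classes are left out. Up to 4 members of each list with the smallest adjusted p, and any fixed marker, may also be named. The groups, comparisons, gene lists, markers, rule for named genes and the alternatives named next were fixed before the data were examined. The thresholds that name clusters were set after the clusters were seen.

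The alternatives named beforehand were RLE size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, nuclei with at least 1000 UMIs, libraries with at least 50 nuclei of a class, removal of nuclei with 3 or more markers of another class (mixed nuclei), TMM on class counts, shares of non-neuronal nuclei, an estimated correlation in camera, and leaving out each library in turn. A pair was added after seeing the data: calls counted only at or above the gene's whole cortex level, and a limma test of each class's difference per library from the mean of the other classes (prior count 2). On simulated data for the day 3 comparison, edgeR recovered 63% of 2-fold and 91% of 4-fold changes in whole cortex, 43% and 90% in astrocyte-like nuclei, and 24% and 78% in fibroblast-like nuclei, with 12, 7 and 13 false calls among 18824, 10827 and 6570 genes. The test of shares recovered 50 of 50 planted rises, with 6 other calls in 1800 tests. The test of a class's difference from the others recovered 98% of 200 planted 4-fold changes, with 29 false calls among 9167 genes. Nuclei outside the 9 classes with enough libraries entered the shares and whole cortex sums only. The scripts used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.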

Results

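Single nuclei of mouse cerebral cortex were profiled by RNA sequencing after occlusion of the distal middle cerebral artery, a stroke model that injures the cortex, or after sham surgery. The 17 libraries fell into 5 groups: sham (n = 3), day 3 (n = 3), day 7 (n = 4), day 14 (n = 3) and day 28 (n = 4). The series concerns cells of the leptomeninges, the membranes on the brain surface, and the mending of blood vessels over time after the occlusion. Libraries held 3244 (day 3 replicate 1) to 8556 nuclei (day 7 replicate 4) and 9919713 to 22934492 UMIs. Named classes with at least 1000 nuclei were excitatory neuron-like (26471 nuclei, median 4376 UMIs), oligodendrocyte-like (10839, 896), astrocyte-like (9710, 1349.5) and microglia or macrophage-like (phagocyte-like below; 9612, 681). The others were striatal neuron-like (9197, 3379), inhibitory neuron-like (8466, 3532), fibroblast-like (3501, 1058), OPC-like (oligodendrocyte precursor; 2840, 1304.5), endothelial-like (2583, 791) and mural-like (1269, 629). Unnamed nuclei made up 3.98% to 33.5% of a library. Values are means over the libraries of a group ± SD, log2 folds are against sham ± SE, and n is as above throughout.

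Immune classes took a larger share of nuclei after occlusion. Phagocyte-like nuclei, the resident and invading phagocytes, rose from 4.61% ± 0.946 in sham to 14.4% ± 1.97 at day 3, which is 3.12-fold (log2 1.64 ± 0.20, adjusted p = 3.36e-05). They stood at 10.3% ± 0.548 at day 7 (adjusted p = 0.000343), 9.63% ± 1.94 at day 14 (adjusted p = 0.000949) and 7.18% ± 1.05 at day 28 (log2 0.64, adjusted p = 0.0177). Lymphocyte-like nuclei were 0.0300% ± 0.0399 of sham nuclei and 0.544% ± 0.186 at day 14 (log2 4.05 ± 0.56, adjusted p = 6.23e-05). They were 0.177% at day 3 (adjusted p = 0.0105), 0.184% at day 7 (adjusted p = 0.00752) and 0.205% at day 28 (adjusted p = 0.00529). Without sham replicate 3 the log2 fold was 5.78 at day 14, 4.26 at day 3 (from 2.53), 4.23 at day 7 (from 2.49) and 4.36 at day 28 (from 2.62). The day 28 rise of phagocyte-like nuclei was not past the threshold without sham replicate 3 (log2 0.49) or day 28 replicate 1 (0.56), nor among non-neuronal nuclei (0.30) or nuclei with at least 1000 UMIs (1.10). The day 3 rise of lymphocyte-like nuclei was not past it without day 3 replicate 3 (log2 2.15).

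Fibroblast-like nuclei, which include those of the leptomeninges, rose from 1.95% ± 0.539 in sham to 5.23% ± 2.59 at day 14 (log2 1.43 ± 0.38, adjusted p = 0.0137). Day 14 replicate 1 held 8.13%, and without it the log2 fold was 0.96 (adjusted p = 0.0757). Newly formed oligodendrocyte-like nuclei rose from 0.345% ± 0.194 to 0.880% ± 0.692 at day 3 (log2 1.40, adjusted p = 0.0378) and 1.03% ± 0.121 at day 7 (log2 1.57, adjusted p = 0.0156). Of these nuclei 94.9% carried 3 or more markers of another class, and 20.0% with oligodendrocyte and OPC markers not counted. Their day 7 call was lost without sham replicate 2 (log2 1.18). At day 3 it was lost without sham replicate 1 (1.5) or 2 (1.01), day 3 replicate 3 (0.58), day 14 replicate 1 or day 28 replicate 1, 2 or 3 (each 1.40). It was also lost with TMM (1.24), a replicate block (1.37) or non-neuronal nuclei as the base (0.99). Endothelial-like nuclei, which line vessels, rose from 2.09% ± 0.569 to 3.67% ± 0.638 at day 3 (log2 0.81, adjusted p = 0.0199). That was lost without sham replicate 1 (0.74) or 3 (0.67), without day 3 replicate 1 (0.68), with TMM (0.61) and among non-neuronal nuclei (0.36).

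OPC-like nuclei made up 2.54% ± 0.188 of sham nuclei and 3.72% ± 1.01 at day 3 (log2 0.54, adjusted p = 0.0403). That call was lost without sham replicate 1 (0.60), 2 (0.52) or 3 (0.50), day 3 replicate 1 (0.31), or any of day 7 replicate 3, day 14 replicate 3 and day 28 replicates 1 to 4 (each 0.54). It was lost too with TMM (0.34), with a replicate block (0.53), in nuclei with at least 1000 UMIs (0.72) or among non-neuronal nuclei (0.076). Shares of the other large classes passed no test against sham. Excitatory neuron-like nuclei stood at 30.2% ± 3.45 in sham and 19.4% ± 1.92 at day 14 (adjusted p = 0.158). Astrocyte-like nuclei stood at 9.08% ± 0.447 in sham and 8.73% ± 1.12 at day 3 (adjusted p = 0.83), and oligodendrocyte-like nuclei at 9.97% ± 2.69 in sham and 13.9% ± 1.68 at day 28 (adjusted p = 0.124). A permutation test of the share over the 5 groups gave adjusted p of 0.00026 for phagocyte-like, 0.00058 for lymphocyte-like, 0.0217 for oligodendrocyte-like and OPC-like, 0.0389 for endothelial-like and 0.0652 for fibroblast-like and newly formed oligodendrocyte-like nuclei.

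**Figure D1:**
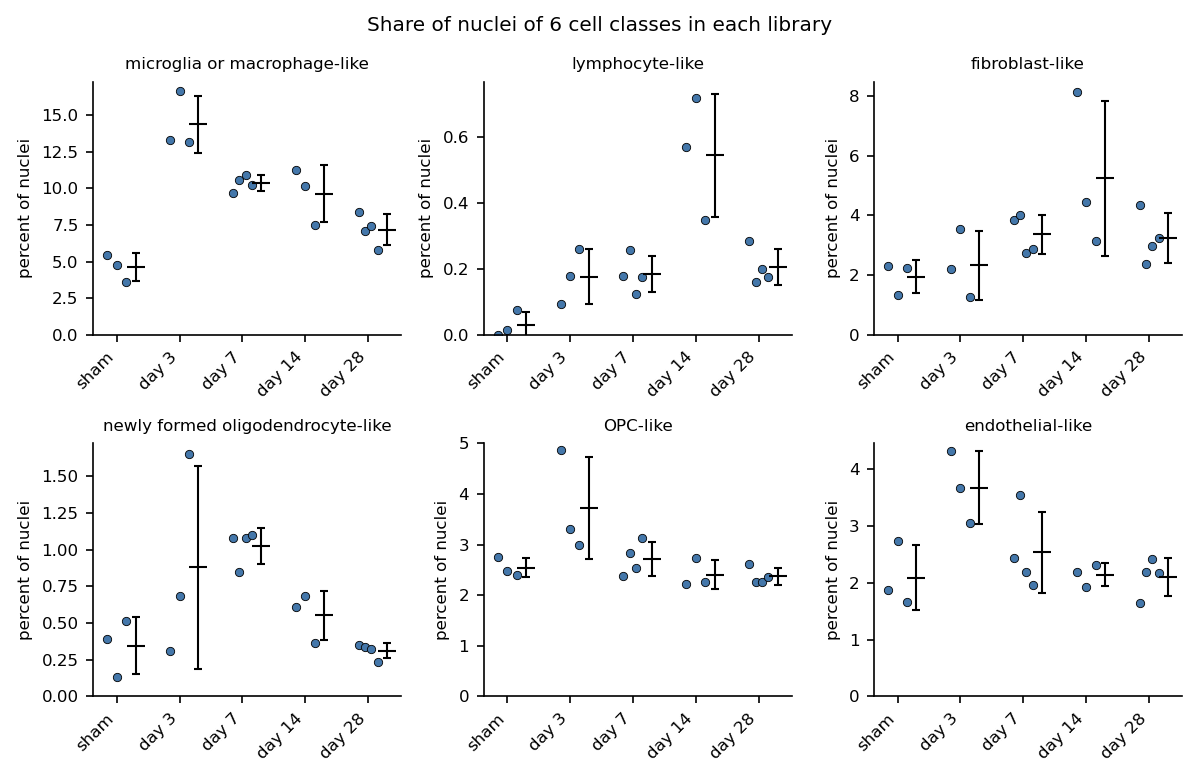
Percent of nuclei in each class per library, by group, with group mean and SD. Phagocyte-like nuclei averaged 4.61% in sham and 14.4% at day 3, and fibroblast-like nuclei 1.95% in sham and 5.23% at day 14.

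In whole cortex, transcripts of reactive glia and phagocytes rose at day 3. Spp1, a secreted phosphoprotein of activated phagocytes (chromosome 5, 104435118 to 104441050, GRCm38), went from 2.11 ± 0.484 to 102 ± 65.9 CPM (log2 5.61 ± 0.77, adjusted p = 7.41e-05). Gpnmb, a lysosomal glycoprotein, rose by log2 5.23 ± 0.90 and Gfap, the intermediate filament of reactive astrocytes, by 3.82 ± 0.40. C4b, a complement factor, went from 3.07 ± 0.479 to 31.4 ± 2.69 CPM (log2 3.35, adjusted p = 3.98e-05). Among the largest falls were Vip, a neuropeptide of interneurons (log2 -2.03 ± 0.25) and Ptgds, a prostaglandin synthase (-1.98 ± 0.27). Of 19013 genes tested, 3842 rose and 3836 fell at day 3.

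Lists of reactive glia, phagocyte and dividing-cell genes rose in whole cortex at day 3, and 14 of the 23 lists passed. Of the proliferation list 22 of 24 measured members rose (adjusted over the list alone, 22), of pan-reactive astrocyte 11 of 13 (11) and of disease-associated microglia 16 of 20 (16). Complement rose in 10 of 14 (10), interferon response in 12 of 22 (15), extracellular matrix in 22 of 33 (24) and blood-brain barrier in 15 of 20 (16). Also passing were disease-associated oligodendrocyte in 11 of 16 (13), A2 astrocyte in 9 of 11 (9), A1 astrocyte in 4 of 11 (4) and neural crest in 4 of 8 (4). Passing too were homeostatic astrocyte with 10 of 18 and 1 fall (11 and 1), homeostatic microglia with 7 of 15 and 1 fall (8 and 1) and angiogenesis with 10 of 21 and 2 falls (10 and 2). Adjusted p for these 14 ranged from 1.69e-15 (proliferation) to 0.0355 (neural crest), and the lowest of them with estimated correlation was 0.173. The 4 neural crest members were Sox9, Ets1, Nes and Tfap2a, which other cells also express. Without day 3 replicate 2 A1 astrocyte (adjusted p 0.137), angiogenesis (0.116) and neural crest (0.132) were lost, the last also without sham replicate 1 (0.0964). Class shares also move whole cortex sums: phagocyte-like and endothelial-like shares rose, while most homeostatic microglia and some blood-brain barrier genes fell within these classes.

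The 9 lists that did not pass in whole cortex at day 3 were antigen presentation class II (3 of 7 rose; adjusted over the list alone, 3), contractile (4 of 12; 4), hypoxia (4 rose and 2 fell of 18; 3 and 2) and heat shock (1 rose and 5 fell of 10; 1 and 5). In axon injury and growth 3 rose and 3 fell of 14 (5 and 4) and in synapse 5 and 1 of 23 (5 and 1). In myelin these were 2 and 4 of 18 (2 and 4), in immediate early 2 and 0 of 18 (0 and 0) and in cholesterol synthesis Fdps and Ebp fell of 23 (0 and 0). Their adjusted p ranged from 0.173 to 0.946, and the median of immediate early was 0.26 while its test pointed down.

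Fewer genes passed in whole cortex at later days. At day 7, 685 rose and 355 fell. Spp1 rose by log2 4.54 ± 0.74, C4b by 3.1 ± 0.40 and Gfap by 3.07 ± 0.38. At day 14, 300 rose and 6 fell, with C4b at log2 2.60 ± 0.41. Interferon response rose in 19 of 22 members at day 7 (22 alone; adjusted p = 6.17e-20). At day 14 it rose in 11 (19; adjusted p = 4.44e-24), both 0.173 with estimated correlation. Of the complement list 9 of 14 rose at day 7 (11; adjusted p = 7.98e-10, and 0.188 with estimated correlation). The C4b call at day 14 was lost without sham replicate 2 or 3 (0.0601 and 0.0628) or day 14 replicate 1 (0.0630), each an adjusted p. The day 7 count of 1040 became 530, 405 and 440 without sham replicate 1, 2 and 3, 1906 without day 3 replicate 1 and 638 and 552 without day 7 replicate 2 and 4. The day 14 count of 306 became 64, 8 and 9 without sham replicate 1, 2 and 3 and 10 and 104 without day 14 replicate 1 and 2. It was 0 with nuclei of at least 1000 UMIs in the edgeR test, where 1395 genes had an unadjusted p under 0.05 (DESeq2 on all nuclei called 496).

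At day 28 a complement gene stayed high in whole cortex. C4b rose by log2 2.66 ± 0.40, Cdk8, a kinase of the transcription mediator complex (chromosome 5, 146231230 to 146302874), went from 382 ± 41.6 to 246 ± 2.70 CPM (log2 -0.63 ± 0.10), and Fbxw15 rose by 1.71 ± 0.27. These 3 calls in the edgeR test each had adjusted p = 0.0499, and Fbxw15 was named after its values were seen. At unadjusted p under 0.05 there were 1966 genes, and DESeq2 called 167. The count became 0 without sham replicate 1, 2 or 3, 15, 0 and 0 without day 3 replicate 1, 2 and 3. It was 0, 0, 5 and 0 without day 7 replicate 1, 2, 3 and 4, 6 and 0 without day 14 replicate 1 and 2 and 0 without day 28 replicate 1, 2 or 3. C4b and Cdk8 were not past the threshold in any fit that gave 0, nor with RLE size factors (0.0697), no filter on low counts (0.0523), a replicate block (0.0938) or nuclei with at least 1000 UMIs (0.104 and 0.102), each an adjusted p. Cdk8 also was not without day 14 replicate 3 (adjusted p 0.0629) or day 28 replicate 4 (0.0751).

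At day 3 many genes moved the same way in all 9 classes tested. Ptgds, a prostaglandin synthase of meninges and oligodendrocytes, fell in oligodendrocyte-like (log2 -2.77 ± 0.26), endothelial-like (-3.71 ± 0.34) and OPC-like nuclei (-3.25 ± 0.36). Of 1564 genes tested in every class, 284 stood above sham in all 9 at day 3 and 256 below, which is 34.5% against 18.9% at day 7, 7.67% at day 14 and 8.31% at day 28. The median log2 fold of the longest tertile of genes exceeded that of the shortest by 0.43 in astrocyte-like to 1.11 in endothelial-like nuclei. Markers of excitatory neurons, read in the 7 non-neuronal classes, stood at 46.2% ± 1.40 of their level in excitatory neuron-like nuclei in sham and 36.9% ± 3.99 at day 3. Without Rorb and Foxp2 they stood at 38.3% ± 3.09 and 22.6% ± 7.37. With all 11 markers the fall was not shared by all classes: it was from 38.9% to 16.6% in endothelial-like, 55.6% to 30.7% in mural-like and 44.2% to 27.1% in phagocyte-like nuclei. In astrocyte-like nuclei they stood at 64.3% and 65.3% (27.0% and 18.9% without Rorb and Foxp2) and in fibroblast-like at 57.9% and 68.5% (32.5% and 15.6%). Median UMIs per nucleus were higher at day 3 than in sham in all 9 classes, at 664 and 1264 in endothelial-like nuclei.

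Summed over the 9 classes, 7921 calls were rises and 8294 falls at day 3, 1100 and 580 at day 7, 254 and 62 at day 14, and 31 and 29 at day 28. When each class was set against the other classes in the same library, the calls were 3904, 648, 222 and 85. Ptgds, which fell past the threshold in all 9 classes at day 3, then passed in none. Its log2 difference was -0.18 in oligodendrocyte-like, -0.78 in endothelial-like, -0.076 in OPC-like and -0.37 in excitatory neuron-like nuclei. It stood the other way in inhibitory neuron-like (0.41), astrocyte-like (0.057), phagocyte-like (0.21), mural-like (0.10) and fibroblast-like nuclei (0.63). The sum of 1680 at day 7 became 984, 585 and 858 without sham replicate 1, 2 and 3 and 2623 without day 3 replicate 1. The sum of 316 at day 14 became 103, 101 and 141 without sham replicate 1, 2 and 3 and 103 and 207 without day 14 replicate 1 and 2. The sum of 60 at day 28 became 29 and 20 without sham replicate 1 and 2, 167 without day 3 replicate 1, 101 without day 7 replicate 3 and 35, 36, 37 and 129 without day 28 replicate 1, 2, 3 and 4.

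**Figure D2:**
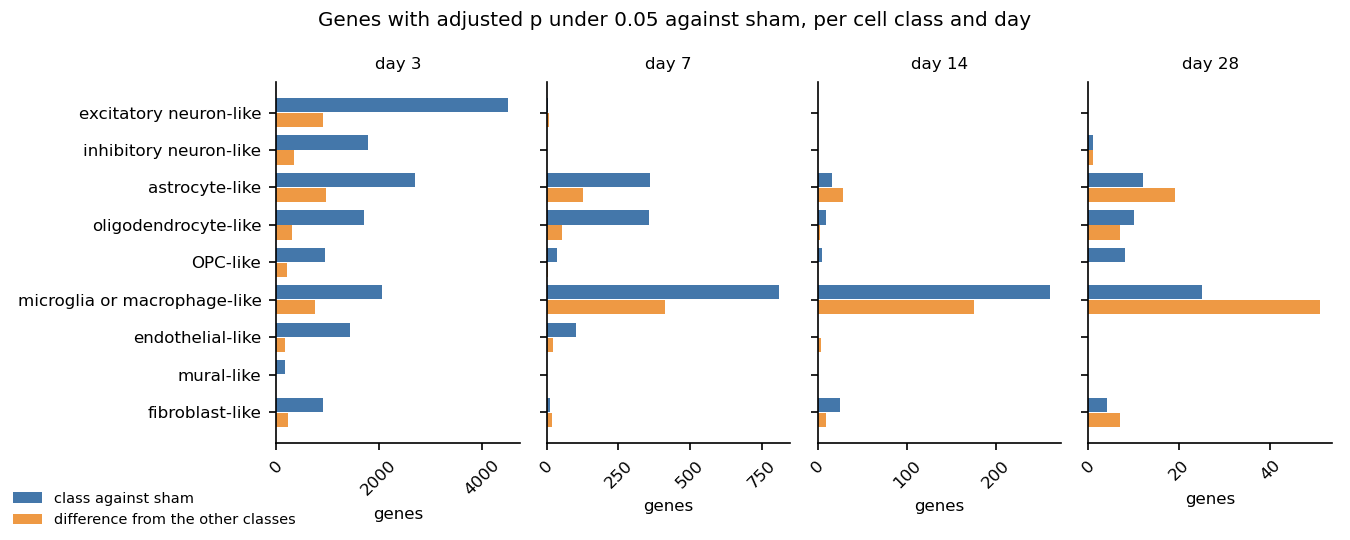
Genes with adjusted p under 0.05 against sham in each class at each day, as bars for the class itself and for its difference from the other classes. At day 3 excitatory neuron-like nuclei had 4501 calls and phagocyte-like nuclei 2059.

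**Figure D3:**
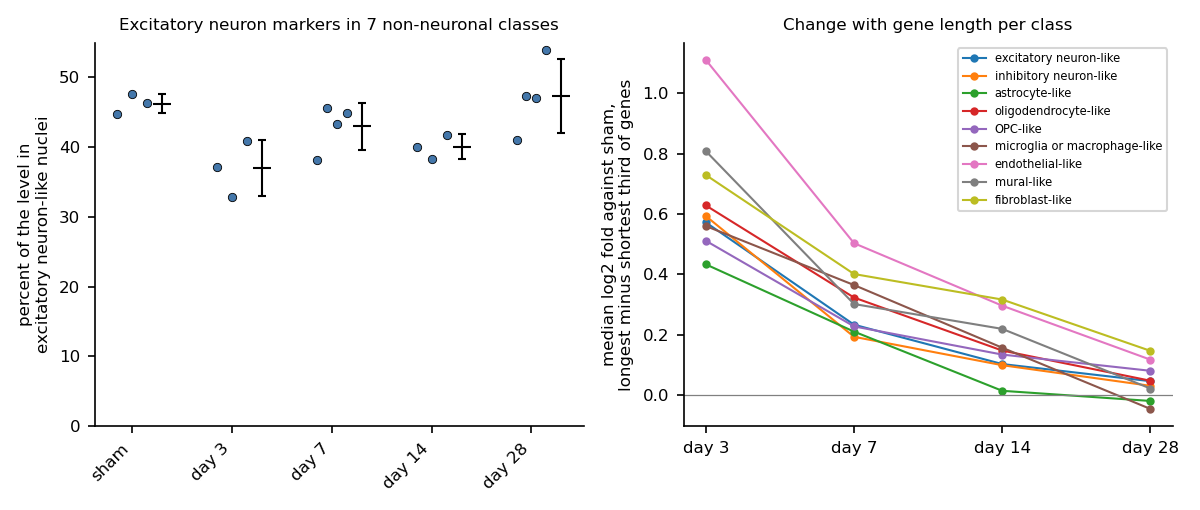
Left, excitatory neuron markers in the 7 non-neuronal classes per library, as percent of their level in excitatory neuron-like nuclei, by group. Right, the median log2 fold of the longest tertile of genes minus that of the shortest, per class and day, which at day 3 ran from 0.43 to 1.11.

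Phagocyte-like nuclei at day 3 held more Gpnmb and Spp1, more genes of dividing cells and less of the genes of resting microglia. Gpnmb, a lysosomal glycoprotein (chromosome 6, 49036546 to 49070929), had 0 UMIs in sham and 1254 at day 3, at least 132-fold higher (adjusted p = 6.64e-06; 74.4-fold without day 3 replicate 2). Spp1 rose by log2 5.99 ± 0.69. Cx3cr1, the fractalkine receptor, went from 1183 ± 15.2 to 529 ± 56.3 CPM (-1.17 ± 0.17).

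By list, 11 of 16 disease-associated microglia genes rose at day 3 (adjusted over the list alone, 12 and 1 fall; adjusted p = 0.000172, and 0.423 with estimated correlation). Of the homeostatic list 13 of 15 genes fell (13; adjusted p = 1.50e-10, and 0.249 with estimated correlation). All 14 proliferation genes rose (14; adjusted p = 3.56e-07, and 0.325 with estimated correlation) and 5 of 16 interferon response genes (5; adjusted p = 0.0215, and 0.684 with estimated correlation). Complement (3 rose and 2 fell of 8; alone 3 and 3; adjusted p = 0.983), antigen presentation class II (0 of 7; adjusted p = 0.894) and cholesterol synthesis (0 of 8; adjusted p = 0.604) did not pass. The median of complement was 0.17 while its test pointed down. Of 8455 genes, 1085 rose and 974 fell at day 3. The nuclei behind these sums differed between groups. Of the class, a cluster with Siglech and Selplg among its top genes held 91.3% in sham and 22.9% at day 3, a second cluster 2.04% and 47.6%. A cluster led by F13a1, a gene of monocyte-derived macrophages, Gpnmb, Spp1 and Thbs1 held 0 nuclei in sham and 335 at day 3, with 46.8% of its nuclei from 1 library.

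Interferon response genes rose in phagocyte-like nuclei at days 7 and 14. At day 7 13 of 16 members rose (adjusted over the list alone, 15; median log2 1.91; adjusted p = 3.06e-11, and 0.249 with estimated correlation) and at day 14 12 (14; median 1.70; adjusted p = 3.12e-14, and 0.224 with estimated correlation). Among them was Ifi204, at log2 3.55 ± 0.58 and 3.6 ± 0.60. Axl, a receptor for dying cells (chromosome 7, 25757273 to 25788705), had 0 UMIs in sham and was at least 14.8-fold higher at day 7 and at least 20.7-fold at day 14. Disease-associated microglia genes rose in 10 and 9 of 16 cases (10 and 11 alone; adjusted p = 7.50e-07 and 8.26e-11, 0.275 and 0.224 with estimated correlation).

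Across all genes of this class 509 rose and 301 fell at day 7, 207 and 53 at day 14, and 19 and 6 at day 28. Apoe, the lipid carrier apolipoprotein E, rose by log2 2.0 ± 0.26 at day 14 and went from 1053 ± 194 to 3362 ± 1019 CPM at day 28 (1.68 ± 0.25, adjusted p = 0.000499). Axl was at least 7.71-fold higher at day 28 (adjusted p = 0.0117). Of the disease-associated list Apoe and Axl rose at day 28 (8 of 16 adjusted over the list alone; adjusted p = 2.72e-08, and 0.249 with estimated correlation). The Axl call at day 28 was lost without sham replicate 1, 2 or 3 (0.0970, 0.119 and 0.0639), each an adjusted p. DESeq2, which gave Axl no adjusted p, did not call it. The day 7 count of 810 became 498, 324 and 484 without sham replicate 1, 2 and 3. The 260 at day 14 became 96, 87 and 129 without sham replicate 1, 2 and 3 and 92 without day 14 replicate 1. The 25 at day 28 became 9, 3 and 16 without sham replicate 1, 2 and 3 and 14, 14 and 58 without day 28 replicate 1, 3 and 4.

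Astrocyte-like nuclei at day 3 held genes of reactive and dividing astrocytes. Gfap (chromosome 11, 102887336 to 102900912) went from 138 ± 23.5 to 1355 ± 318 CPM (log2 3.29 ± 0.34, adjusted p = 2.34e-07) and Vim, also an intermediate filament, rose by 4.66 ± 0.45. Timp1, an inhibitor of matrix proteases, and Lcn2, an iron-binding lipocalin, had 0 UMIs in sham and were at least 30.9-fold and 25.8-fold higher (Lcn2 16.8-fold without day 3 replicate 2). Set against the other classes in the same libraries, Gfap differed by log2 0.42 (adjusted p = 0.287).

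By list, all 11 pan-reactive astrocyte genes rose at day 3 (adjusted over the list alone, 11; median log2 4.52; adjusted p = 2.04e-09, and 0.224 with estimated correlation), all 5 A2 genes (5; adjusted p = 3.91e-05, and 0.224 with estimated correlation). So did all 18 proliferation genes (18; adjusted p = 2.44e-17, and 0.224 with estimated correlation), 12 of 20 extracellular matrix genes (13; adjusted p = 2.33e-06, and 0.224 with estimated correlation). Also rising were 7 of 16 interferon response genes with 1 fall (9 and 1; adjusted p = 0.0112, and 0.489 with estimated correlation) and 2 of 5 A1 genes (3; adjusted p = 0.0495, and 0.325 with estimated correlation). Of the cholesterol synthesis list 8 of 22 fell (10; adjusted p = 6.61e-05, and 0.489 with estimated correlation). Homeostatic astrocyte genes did not pass (5 rose and 2 fell of 18; alone 6 and 3; adjusted p = 0.184). The A1 call was lost without sham replicate 2 or 3 (0.0981 and 0.0504), day 3 replicate 2 or 3 (0.0725 and 0.0713) or day 28 replicate 2 (0.0505), each an adjusted p. In all 1440 genes rose and 1249 fell of 11136, and of the astrocyte-like nuclei 1 cluster held 88.6% in sham and 23.8% at day 3 while another held 0 nuclei in sham and 569 at day 3 (43.6%).

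Interferon response genes rose in astrocyte-like nuclei at day 7, 13 of 16 (adjusted over the list alone, 15; median log2 2.25; adjusted p = 5.25e-17, and 0.224 with estimated correlation). Oasl2, an antiviral enzyme (chromosome 5, 114896936 to 114912234), with 1 sham UMI, was 81.4-fold (95% counting interval 14.4 to 3238) higher. Pan-reactive genes rose in 7 of 11 cases at day 7 (11 alone; adjusted p = 4.40e-10, and 0.224 with estimated correlation) and 2 at day 14 (9 alone; adjusted p = 1.62e-11, and 0.224 with estimated correlation). At day 28 0 passed over all genes and 9 over the list alone (median 1.80; adjusted p = 9.35e-07, and 0.275 with estimated correlation).

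Gfap stood at 771 ± 279 CPM at day 7 and 437 ± 153 at day 14 (log2 1.66, adjusted p = 0.0315) in astrocyte-like nuclei. At day 28 C4b rose by log2 1.73 ± 0.28. Over all genes of the class 262 rose and 97 fell at day 7, 16 and 0 at day 14, and 7 and 5 at day 28. As differences from the other classes Gfap at day 7 (log2 -0.33) and day 14 (-0.13) and C4b at day 28 (-0.22) stood the other way. The Gfap call at day 14 was lost without mixed nuclei (log2 1.54) and without sham replicate 1, 2 or 3 (adjusted p 0.211, 0.325 and 0.0935), day 14 replicate 1 or 2 (0.0977 and 0.271) or day 28 replicate 2 (0.0524). At day 28 C4b was lost without sham replicate 1 or 2 (adjusted p 0.0899 and 0.114) or day 28 replicate 2 or 3 (0.0615 and 0.0829). The day 7 count of 359 became 162, 138 and 160 without sham replicate 1, 2 and 3, 617 without day 3 replicate 1 and 213 without day 7 replicate 2. The 16 at day 14 became 1, 1 and 3 without sham replicate 1, 2 and 3, 55 without day 3 replicate 1, 0, 0 and 28 without day 14 replicate 1, 2 and 3 and 26 without day 28 replicate 4. The 12 at day 28 became 3, 0 and 7 without sham replicate 1, 2 and 3, 69 and 20 without day 3 replicate 1 and 2, 35 without day 7 replicate 3 and 3, 0, 0 and 43 without day 28 replicate 1, 2, 3 and 4.

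**Figure D4:**
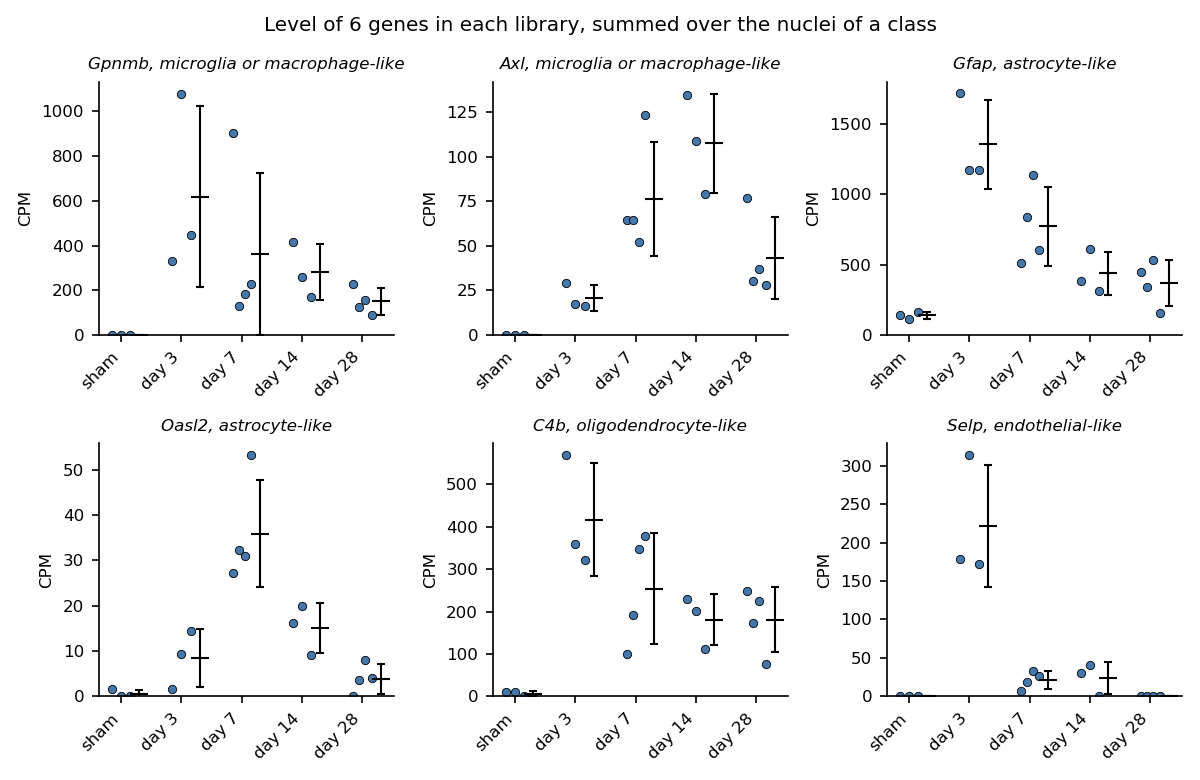
CPM per library, by group, of Gpnmb and Axl in phagocyte-like, Gfap and Oasl2 in astrocyte-like, C4b in oligodendrocyte-like and Selp in endothelial-like nuclei, with group mean and SD.

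Oligodendrocyte-like nuclei held more C4b and Serpina3n and less Opalin and Ermn at day 3. C4b (chromosome 17, 34728380 to 34743882) went from 6.59 ± 5.71 CPM in sham to 416 ± 133 at day 3 (log2 5.76 ± 0.55, adjusted p = 9.91e-09). It was 254 ± 131 at day 7, 181 ± 61.1 at day 14 and 181 ± 75.9 at day 28 (4.6 ± 0.56, adjusted p = 1.85e-05). Serpina3n, a serine protease inhibitor, rose by 5.35 ± 0.69 at day 3. Opalin and Ermn, proteins of mature oligodendrocytes, fell by 0.89 ± 0.16 and 0.70 ± 0.15. Of the class, 1 cluster held 63.6% in sham and 32.0% at day 3, and another 13.2% and 53.5%.

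Disease-associated oligodendrocyte genes rose in 7 of 13 cases at day 3 (adjusted over the list alone, 8; adjusted p = 0.000836, and 0.346 with estimated correlation), 5 at day 7 (10; adjusted p = 2.14e-05, and 0.249 with estimated correlation). They rose in 3 at day 14 (6; adjusted p = 1.27e-05, and 0.249 with estimated correlation) and C4b alone at day 28 (7; adjusted p = 0.000480, and 0.325 with estimated correlation). Interferon response genes rose in 4 of 7 cases at day 7 (6; adjusted p = 3.35e-07, and 0.224 with estimated correlation). Of heat shock genes 3 of 6 fell at day 3 (4; adjusted p = 0.00635, and 0.249 with estimated correlation), and against the other classes these 3, Hspa8, Hsp90aa1 and Hspe1, stood the other way (log2 0.11, 0.25 and 0.11). Myelin genes did not pass at day 3 (4 rose and 5 fell of 18; alone 4 and 6; adjusted p = 0.817), with a median of 0.061 and a test that pointed down. Cholesterol synthesis genes were lower as a list at day 14 (median -0.50; adjusted p = 3.46e-06, and 0.249 with estimated correlation), with 0 of 18 past the threshold over all genes and 1 alone. Over all genes 804 rose and 898 fell of 8970 at day 3, 225 and 133 at day 7, 10 and 0 at day 14, and 3 and 7 at day 28. The day 3 count of 1702 became 1125 without day 3 replicate 1. The 358 at day 7 became 92 and 161 without sham replicate 2 and 3 and 180 and 208 without day 7 replicate 3 and 4. The 10 at day 14 became 2, 1 and 2 without sham replicate 1, 2 and 3, 20 and 19 without day 3 replicate 1 and 3 and 1, 6 and 36 without day 14 replicate 1, 2 and 3. The 10 at day 28 became 6 without sham replicate 2, 29 without day 3 replicate 1, 18 without day 7 replicate 3 and 6 without day 28 replicate 3.

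OPC-like nuclei held more genes of cell division at day 3. C4b had 0 UMIs in sham and was at least 23.2-fold higher at day 3 (adjusted p = 2.40e-08) and at least 12.3-fold at day 14 (adjusted p = 0.000753). All 12 proliferation genes rose at day 3 (adjusted over the list alone, 12; adjusted p = 3.64e-09, and 0.249 with estimated correlation), with Mki67 at log2 3.1 ± 0.50. Srebf2 and Fdft1 of the cholesterol synthesis list (5 measured) rose at day 3 (5 alone; adjusted p = 0.0216, and 0.423 with estimated correlation), a list call lost without day 3 replicate 1 (0.0993). Both gene calls were lost with DESeq2 (adjusted p 0.0971 and 0.127), without sham replicate 1 (0.117 and 0.259) or 2 (0.104 and 0.113) or day 3 replicate 1 (0.105 and 0.296). Fdft1 was also lost without day 7 replicate 2, day 14 replicate 2 or 3 or day 28 replicate 1, 2 or 3 (0.0518 to 0.0580). Cmss1 fell by 0.81 ± 0.11 at day 28 (adjusted p = 3.21e-06). Over all genes 445 rose and 506 fell of 6003 at day 3, 24 and 12 at day 7, and 2 and 6 at day 28. The day 14 calls were C4b, Glis3 (log2 3.77), Bmpr1b (2.93), Gfap (3.35) and Nkain2 (1.13), and Gfap and Nkain2 were named after their values were seen. Bmpr1b was lost without sham replicate 1, 2 or 3 (0.118, 0.151 and 0.227) or day 14 replicate 1 or 2 (0.210 and 0.364), each an adjusted p, and with DESeq2 (adjusted p = 0.369), as was Glis3 (0.157). Against the other classes Mki67, Top2a and Diaph3 at day 3 stood the other way (log2 -0.26, -1.05 and -0.18), and C4b (adjusted p = 0.891) and Bmpr1b at day 14 (0.434) and Cmss1 at day 28 (0.933) did not pass. The day 3 count of 951 became 629 without day 3 replicate 1. The 36 at day 7 became 15, 8 and 13 without sham replicate 1, 2 and 3, 66 without day 3 replicate 1 and 21 and 20 without day 7 replicate 1 and 3. The 5 at day 14 became 3, 2 and 3 without sham replicate 1, 2 and 3, 14 without day 3 replicate 1, and 3 and 8 without day 14 replicate 1 and 3. The 8 at day 28 became 3 without sham replicate 2, 16 without day 3 replicate 1 and 4 without day 28 replicate 2.

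Excitatory neuron-like nuclei held more Spp1 at day 3, as did whole cortex. Spp1 went from 0.571 ± 0.309 to 30.7 ± 16.7 CPM (log2 5.71 ± 0.79, adjusted p = 0.000341; 5.61 in whole cortex), and over all libraries stood at 34.0% of its whole cortex level. Of the synapse list 9 rose and 2 fell of 23 (adjusted over the list alone, 10 and 2; median log2 0.15, against 0.23 for the longest tertile of genes; adjusted p = 0.0205, and 0.423 with estimated correlation), a call lost without sham replicate 3 (0.0565). Of heat shock genes 4 of 6 fell (4 alone; adjusted p = 0.0422, and 0.489 with estimated correlation). That was lost without sham replicate 2 or 3 (adjusted p 0.0859 and 0.0666), day 3 replicate 2 or 3 (0.0809 and 0.120) or day 14 replicate 2 or 3 (0.050 and 0.0596). Against the other classes Hspe1, Hspa8 and Hsp90aa1 stood the other way (log2 0.060, 0.51 and 0.62). Interferon response genes were higher as a list at day 14 (median 0.70; 0 of 13 rose over all genes and 5 alone; adjusted p = 5.75e-07, and 0.224 with estimated correlation) and immediate early genes at day 28 (median 0.71; 0 of 18 and 1 alone; adjusted p = 3.81e-09, and 0.325 with estimated correlation). Gfap, an astrocyte gene named here after its values were seen, also rose at day 3 (log2 3.62 ± 0.46). Over all libraries it stood at 23.3% of its whole cortex level.

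Over all genes of excitatory neuron-like nuclei 2193 rose and 2308 fell of 15761 at day 3. Of the class, 1 cluster held 35.9% in sham and 21.3% at day 3, and its part in these calls was not tested. At day 7 Spp1 (log2 5.08), Gfap (3.38) and Aqp4, a water channel of astrocytes (1.76), rose and Kbtbd11 fell (-0.48), with Gfap and Aqp4 named after their values were seen, and DESeq2 called 237. In edgeR 0 genes passed at day 14 (527 at unadjusted p under 0.05; DESeq2 0) and 0 at day 28 (1107; DESeq2 19). The Spp1 call was lost without sham replicate 1, 2 or 3 (adjusted p 0.116, 0.168 and 0.157), day 7 replicate 4 (0.121), day 14 replicate 2 (0.0726) or day 28 replicate 1, 2 or 4 (0.0759, 0.0587 and 0.0580). Kbtbd11 was lost without sham replicate 1, 2 or 3 (0.138, 0.168 and 0.0665), day 3 replicate 2 (0.0561), day 7 replicate 2 or 4 (0.113 and 0.121), day 14 replicate 1, 2 or 3 (0.0645, 0.0726 and 0.0523) or day 28 replicate 1, 2 or 4 (0.0759, 0.0587 and 0.0580), each an adjusted p. Kbtbd11 was also lost with no filter on low counts (-0.50), with a replicate block (-0.48), without mixed nuclei (-0.46) or as a difference from the other classes (-0.20), each a log2 fold. The day 7 count of 4 became 0 without sham replicate 1, 2 or 3, 395 and 2 without day 3 replicate 1 and 2, 10, 198 and 1 without day 7 replicate 1, 3 and 4. It was 1 without day 14 replicate 2 and 1 without day 28 replicate 1, 2 or 4, and the day 28 count 5 without day 3 replicate 1 and 1 without day 7 replicate 3.

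In inhibitory neuron-like nuclei Vip went from 162 ± 53.2 to 33.8 ± 18.0 CPM at day 3 (log2 -2.24 ± 0.41, adjusted p = 0.00347). Of the synapse list 6 of 23 rose (11 and 1 fall alone; adjusted p = 0.000353, and 0.350 with estimated correlation). Of these Syn1, Stx1a, Shank2 and Shank3 were lost without day 3 replicate 1 (adjusted p 0.0785 to 0.187), and each without some sham library. Of heat shock 3 of 6 fell (5 alone; adjusted p = 0.00957, and 0.423 with estimated correlation). Against the other classes Vip did not pass (log2 -0.69, adjusted p = 0.227) and Shank3, Hspe1, Hspa8 and Hsp90aa1 stood the other way (-0.38, 0.24, 0.31 and 0.44). Over all genes 810 rose and 980 fell of 12265 at day 3. In edgeR 0 passed at day 7 (1063 at unadjusted p under 0.05; DESeq2 3), 0 at day 14 (344; DESeq2 0), and at day 28 Gm19951 fell by 1.03 ± 0.13 (adjusted p = 0.00353), a gene named after its values were seen. The day 3 count of 1790 became 1157, 1023 and 684 without sham replicate 1, 2 and 3 and 586 without day 3 replicate 1. At day 7 counts were 3 without day 3 replicate 1, 1 and 5 without day 7 replicate 1 and 3 and 2 without day 28 replicate 4, and at day 28 0 without sham replicate 2 and 3 without day 3 replicate 1.

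Endothelial-like nuclei at day 3 held Selp, more extracellular matrix genes and less Mfsd2a and Slc7a5. Selp, P-selectin, which catches passing leukocytes (chromosome 1, 164115264 to 164150026), had 0 UMIs in sham and 197 at day 3, at least 22.7-fold higher (adjusted p = 1.34e-06). Extracellular matrix genes rose in 7 of 8 cases (adjusted over the list alone, 8; adjusted p = 8.82e-05, and 0.249 with estimated correlation). As a difference from the other classes Col4a1 and Fn1 stood the other way (log2 -0.0067 and -0.66) and Col4a2 did not pass (0.12). Mfsd2a, a lipid transporter of the barrier, fell by 1.71 ± 0.31 and Slc7a5, an amino acid transporter, by 1.27 ± 0.24. They were 2 of the 6 blood-brain barrier genes that fell of 20 (6 alone), a list that did not pass (adjusted p = 0.10). Angiogenesis (1 rose and 2 fell of 9; adjusted p = 0.973) had a median of 0.043 and a test that pointed down.

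Over all genes of endothelial-like nuclei 664 rose and 771 fell of 5026 at day 3 and 75 and 28 at day 7. In edgeR 0 genes passed at day 14 (395 at unadjusted p under 0.05; DESeq2 1) and 0 at day 28 (315; DESeq2 2). The day 3 count of 1435 became 777 without sham replicate 2. The 103 at day 7 became 57, 11 and 31 without sham replicate 1, 2 and 3, 166 without day 3 replicate 1 and 63 and 30 without day 7 replicate 1 and 4. Counts were 1 without day 14 replicate 3 at day 14 and 7 and 3 without day 3 replicate 1 and 2 at day 28.

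Mural-like nuclei, those of pericytes and vessel muscle, held more matrix genes at day 3. Extracellular matrix genes rose in 4 of 6 cases (adjusted over the list alone, 4; adjusted p = 0.00121, and 0.224 with estimated correlation). Against the other classes Col4a1 stood the other way (log2 -0.11), and Col4a2, Col8a1 and Lama2 did not pass (0.55, 1.08 and 0.54). All 4 calls were lost without sham replicate 2 (adjusted p 0.107, 0.0609, 0.0534 and 0.0534) or day 3 replicate 2 (0.120, 0.0508, 0.237 and 0.0607). Col4a1, Col8a1 and Lama2 were lost without sham replicate 3 (0.184, 0.0957 and 0.0966) or day 3 replicate 1 (0.135, 0.0568 and 0.0907) and with libraries of at least 50 nuclei (0.117, 0.0576 and 0.0914), and Col4a1 and Col8a1 without sham replicate 1 (0.0510 and 0.0700). Col4a1 was also lost with DESeq2 (0.0602) and without day 7 replicate 4, day 14 replicate 1 or day 28 replicate 4 (0.0515 to 0.0562). Contractile genes were lower as a list at day 14 (median -1.42; 0 of 5 over all genes and 3 alone; adjusted p = 0.00125, and 0.249 with estimated correlation). Of 1861 genes 55 rose and 115 fell at day 3, a count of 170 that became 72 and 61 without sham replicate 2 and 3 and 44, 78 and 268 without day 3 replicate 1, 2 and 3. In edgeR 0, 0 and 0 genes passed at days 7, 14 and 28 (156, 86 and 123 at unadjusted p under 0.05; DESeq2 0, 0 and 0).

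Fibroblast-like nuclei at day 3 held more extracellular matrix and proliferation genes. Fbn1, fibrillin, went from 95.4 ± 10.6 to 405 ± 46.0 CPM (log2 2.10 ± 0.30, adjusted p = 0.000105). Of the extracellular matrix list 10 rose and 2 fell of 30 (adjusted over the list alone, 12 and 2; adjusted p = 0.00121, and 0.591 with estimated correlation). Of proliferation 4 of 5 rose (5; adjusted p = 0.000560, and 0.249 with estimated correlation). Of these Mki67 was lost without sham replicate 1 or 3 (0.0582 and 0.117) or day 3 replicate 2 (0.122), each an adjusted p. Top2a was lost with DESeq2 (0.0544), in nuclei with at least 1000 UMIs (0.0830) and without sham replicate 2 or 3 (0.0562 and 0.0948) or day 3 replicate 2 (0.407). Cenpe was lost with DESeq2 (0.0673) and without sham replicate 2 or 3 (0.0633 and 0.175). As a difference from the other classes all 3 stood the other way (log2 -0.63, -1.95 and -0.50). Neural crest (0 of 3; adjusted p = 0.973) and contractile genes (0 of 5; adjusted p = 0.772) did not pass. Interferon response genes were higher as a list at day 14 (median 0.80; 0 of 10 over all genes and 6 alone; adjusted p = 7.98e-05, and 0.224 with estimated correlation).

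Of the fibroblast-like nuclei, a cluster with Ranbp3l among its top genes held 62.2% in sham, 36.0% at day 3 and 36.0% at day 14, and a cluster with Bnc2 and Tbx15 among them held 37.8%, 64.0% and 64.0%. Over all genes 425 rose and 493 fell of 6975 at day 3, 2 (Adamts12 and Prr16) and 8 at day 7, and 16 and 9 at day 14. Adamts12 was lost without sham replicate 3 (0.103) or mixed nuclei (0.0534), each an adjusted p. Prr16 was lost without sham replicate 1 or 3 (0.364 and 0.109) or day 7 replicate 1 or 2 (0.0648 and 0.0612), in nuclei with at least 1000 UMIs (0.143) and as a difference from the other classes (0.0568). At day 28 Cdk8 (log2 -1.15 ± 0.17, adjusted p = 0.00173), Slc6a6 (-1.71 ± 0.29), Col6a1 (-2.0 ± 0.38) and Cmss1 (-0.82 ± 0.16) fell, the last named after its values were seen. Slc6a6 was lost without sham replicate 1 (0.174) and Col6a1 without sham replicate 1 (0.504), day 7 replicate 2 or 4 (0.0514 and 0.0517) or day 28 replicate 1, 2 or 4 (0.137, 0.0708 and 0.0612), each an adjusted p. Col6a1 was also lost without mixed nuclei (log2 -1.57), and Cdk8 as a difference from the other classes (-0.36). The day 3 count of 918 became 605 without sham replicate 3 and 449 without day 3 replicate 2. The 10 at day 7 became 2 without sham replicate 1 and 6 and 18 without day 7 replicate 2 and 3. The 25 at day 14 became 1, 10 and 4 without sham replicate 1, 2 and 3, 38 without day 7 replicate 1 and 7 without day 14 replicate 1. The 4 at day 28 became 1 and 8 without sham replicate 1 and 2, 2 without day 7 replicate 2 or 4 and 10 and 8 without day 28 replicate 3 and 4.

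**Figure D5:**
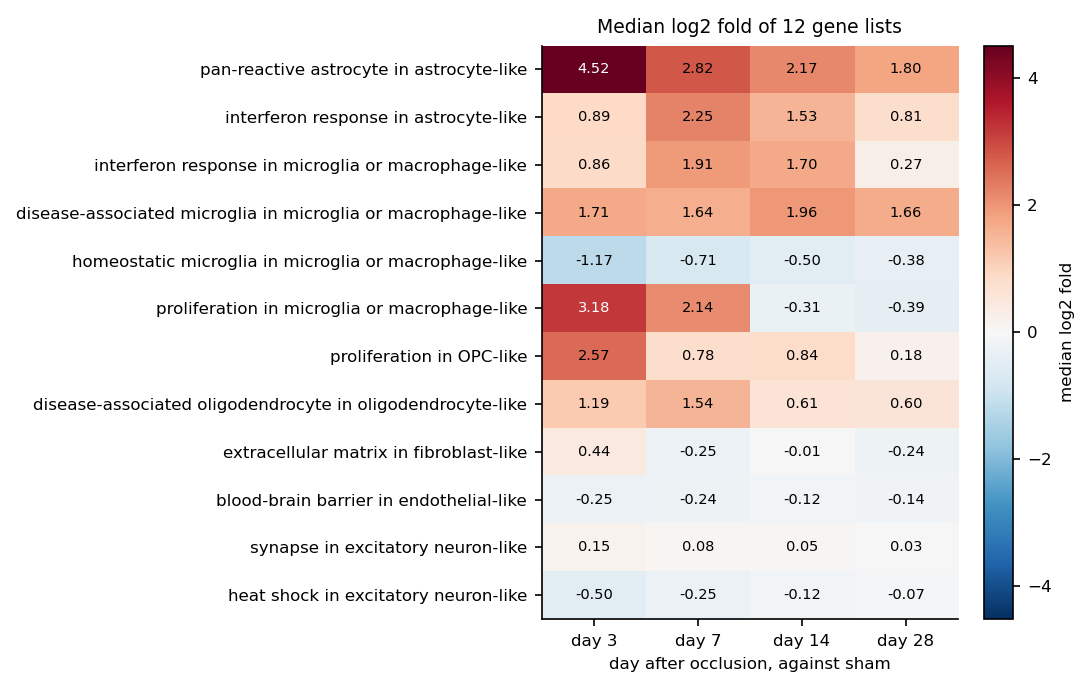
Median log2 fold against sham of 12 gene lists per day, each in the class named beside it, with genes at 0 UMIs in sham set at their lower bound. Pan-reactive astrocyte genes in astrocyte-like nuclei had a median of 4.52 at day 3 and 1.80 at day 28, and interferon response genes in phagocyte-like nuclei 1.91 at day 7.

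Between day 3 and day 28 reactive genes such as Gfap and Spp1 fell and Cx3cr1, a gene of resting microglia, rose. Phagocyte-like nuclei took a lower share at day 28 (log2 -1.0 ± 0.18, adjusted p = 0.000888), as did newly formed oligodendrocyte-like (-1.55, adjusted p = 0.0156), endothelial-like (-0.80, adjusted p = 0.0156) and OPC-like nuclei (-0.64, adjusted p = 0.0137). Oligodendrocyte-like nuclei took a higher one (0.66, adjusted p = 0.0266). In astrocyte-like nuclei Gfap was lower by log2 1.88 ± 0.28 and Vim by 2.91 ± 0.34, and in phagocyte-like nuclei Spp1 was lower by 4.27 ± 0.46 and Cx3cr1 higher by 0.99 ± 0.15. Summed over the 9 classes, 15932 calls passed, 8203 higher and 7729 lower at day 28. The oligodendrocyte-like call was lost without day 3 replicate 1, 2 or 3 (0.70, 0.60 and 0.68) or day 28 replicate 1, 2 or 3 (0.66, 0.62 and 0.62). The newly formed call was lost without day 3 replicate 3 (-0.73), OPC-like without day 3 replicate 1 (-0.41) and endothelial-like without day 3 replicate 1 (-0.67) or day 28 replicate 1 (-0.70), each with its log2 fold. In nuclei with at least 1000 UMIs the oligodendrocyte-like (0.32) and OPC-like calls (-0.55) were also lost, and with TMM the OPC-like (-0.47) and endothelial-like ones (-0.61).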

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

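Tests chosen only after results were seen were leaving out 1 library (shared day 3 shift, fibroblast-like share), gene length, fibroblast-like clusters and the count filter for mixed nuclei. The tests of free RNA, mixed nuclei and other splits were set before.

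Of 106 groups of 4 libraries, 11 held a library far from the other 3, where chance gives about 1 in 20 groups. At day 7 these were the newly formed oligodendrocyte-like share in replicate 2 (0.844% of nuclei, the nearest library 1.08%), Piezo2 in OPC-like nuclei of replicate 3 (101 CPM, nearest 17.7), and in replicate 1 Gpnmb in phagocyte-like nuclei (905 CPM, nearest 229.7) and Tmem160 in endothelial-like nuclei (20.4, nearest 46.7). At day 28 they were the number of nuclei (4592, nearest 6812) and of UMIs (12911312, nearest 19315159) in replicate 1, the mural-like share in replicate 2 (1.22%, nearest 1.39%), the astrocyte-like share in replicate 4 (10.4%, nearest 9.37%), Fbxw15 in oligodendrocyte-like nuclei of replicate 2 (264 CPM, nearest 173), and in replicate 4 Fam214a in oligodendrocyte-like (116, nearest 153) and Myo18b in phagocyte-like nuclei (68.6, nearest 23.6).

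Day 28 and day 3 differed in the test of the difference itself in 5 class shares and in many genes. The log2 differences, day 28 minus day 3, were -0.64 for OPC-like (adjusted p = 0.0137), -0.80 for endothelial-like (0.0156), -1.0 for phagocyte-like (0.000888), -1.55 for newly formed oligodendrocyte-like (0.0156) and 0.66 for oligodendrocyte-like nuclei (0.0266), in edgeR fits with 3 and 4 libraries. Summed over 9 classes, which counts a gene once per class, 15932 calls passed, and 1 of 35 splits of the same libraries, the real one, gave as many (highest other 5279), so chance can be excluded.

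Genes moved 1 way in all classes at day 3, among them Ptgds, which fell. Day 3 replicate 1 alone is argued against for the summed calls only, of which 70.2% of 16215 were left without it. In inhibitory neuron-like nuclei 586 of 1790 and in mural-like 44 of 170 were left. The shared direction was not recounted. Less free RNA at day 3 stays open: all 3 day 3 libraries lay below all 3 sham libraries (highest minus lowest -3.87 percentage points). That is a mean over 7 classes: in astrocyte-like and fibroblast-like nuclei the level fell only without Rorb and Foxp2. A shift from short to long genes stays open too, with a lowest difference over the classes of 0.43 between the longest and the shortest tertile. Deeper nuclei at day 3 and a response of many cell types, which the design varies together with tissue state, also stay open as untested.

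Genes of reactive astrocytes, Gfap and Vim among them, rose in excitatory neuron-like nuclei at day 3. Without nuclei with 3 or more markers of another class the 9 pan-reactive members kept 118% of their median log2 fold. The 7 that rose still passed, with Lcn2 at 4.57 (from 5.11) and Timp1 at 1.77 (from 2.13). Most removed nuclei had OPC markers (22.3% of the class, of 30.7% removed), so neurons mixed with few astrocyte markers stay open. Free RNA from reactive glia cannot be told apart from expression in the neurons. The members' median fold minus that in whole cortex was -0.66, beyond the preset bound of 0.5 but by less than its spread (0.35). That spread was defined after the value was seen, and free RNA itself moved by log2 -0.32, or -0.76 without Rorb and Foxp2. A response of the neurons to the occlusion stays open as untested.

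The fibroblast-like share rose at day 14 (log2 1.43, adjusted p = 0.0137). More of the brain surface in the day 14 tissue cannot be told apart from a rise. The folds of the 2 fibroblast-like clusters differed by 1.47 (spread 0.60), past the bound of 0.5, at 2.16 for the cluster with Bnc2 and Tbx15 and 0.68 for that with Ranbp3l. The bound was wrong, because the clusters already differed by 1.504 at day 3, when the class share had not risen (log2 0.26, adjusted p = 0.81). Day 14 replicate 1 as the cause cannot be told apart from a rise: without it the log2 fold was 0.96 (spread 0.37, adjusted p = 0.0757), above 0.5 of its value but no longer past the threshold. A biological rise after the occlusion stays open, as untested.

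Other splits of the same libraries were counted for each edgeR count against sham, on any day and at day 28 against day 3, with no adjustment for the number of counts tested. At days 3 and 14 the 10 splits were too few for a share under 0.05, with 1 split, the real one, at each real value. At day 3 the real counts were 7678 in whole cortex, 4501 in excitatory neuron-like, 1790 in inhibitory neuron-like, 2689 in astrocyte-like, 1702 in oligodendrocyte-like, 951 in OPC-like, 2059 in phagocyte-like, 1435 in endothelial-like, 170 in mural-like, 918 in fibroblast-like nuclei and 16215 in their sum. The highest other was 0 in each, except 1 in fibroblast-like nuclei and the sum. Real against highest other were, at day 14, 306 against 0 (whole cortex), 16 against 0 (astrocyte-like), 10 against 1 (oligodendrocyte-like), 5 against 0 (OPC-like), 260 against 0 (phagocyte-like), 25 against 0 (fibroblast-like) and 316 against 3 (sum).

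At day 7 the real split alone, 1 of 35, reached its count in whole cortex (1040 against 21), astrocyte-like (359 against 49), oligodendrocyte-like (358 against 132), OPC-like (36 against 12), phagocyte-like (810 against 380), endothelial-like (103 against 14), fibroblast-like nuclei (10 against 4) and the sum (1680 against 478). The same held at day 28 in oligodendrocyte-like (10 against 2) and OPC-like nuclei (8 against 5), and in 1 of 100 splits for changes on any day in the sum (11972 against 7848), whole cortex (6339 against 4069), excitatory neuron-like (2825 against 2169), inhibitory neuron-like (711 against 422), astrocyte-like (2276 against 1498), oligodendrocyte-like (1400 against 649), OPC-like (791 against 543), phagocyte-like (2043 against 936), endothelial-like (1166 against 1009), mural-like (50 against 44) and fibroblast-like nuclei (710 against 578). For day 28 against day 3 it held in 1 of 35 splits in whole cortex (7415 against 2629), excitatory neuron-like (4283 against 130), inhibitory neuron-like (1934 against 76), astrocyte-like (2633 against 1210), oligodendrocyte-like (1729 against 827), OPC-like (904 against 423), phagocyte-like (2154 against 1458), endothelial-like (1379 against 811), mural-like (120 against 2) and fibroblast-like nuclei (796 against 344). In whole cortex at day 28 the real split alone also had the most calls (3 against 2), but the count was 0 without any 1 sham library, so chance stays open there too. Chance was not excluded, with 2 of 35 splits at the real count, in excitatory neuron-like nuclei at day 7 (4 against 114) and at day 28 in the sum (60 against 68), astrocyte-like (12 against 28), phagocyte-like (25 against 36), fibroblast-like (4 against 5) and inhibitory neuron-like nuclei (1 against 1). The split with 114 calls, many times the real count, points to a structure of the samples: it set the 3 sham libraries and 1 day 7 library against the other 3 day 7 libraries.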

How the results depend on the processing

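Only the added pair of alternatives was chosen after seeing the data. Of log2 folds of named genes, 4062 under other settings kept direction and side of the threshold, 415 only direction, and 54 turned. All 54 were differences from the other classes, a different quantity, while the folds themselves did not turn. With 1 library left out the counts were 10875, 962 and 1. Gene list calls were kept in 324 cases and lost in 174, and with 1 library left out in 2687 and 135. Nuclei with at least 1000 UMIs gave no gene counts for phagocyte-like and mural-like nuclei or the class sum. DESeq2, the count filter and RLE size factors were applied to genes, and TMM and the non-neuronal base to shares. Below, more and fewer mean by over 1.5 times. The cause of these changes was not tested.

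With DESeq2 more genes passed: whole cortex day 7 1638, day 14 496, day 28 167, excitatory neuron-like day 7 237, day 28 19, inhibitory neuron-like any day 1195, day 7 3, day 28 4. Astrocyte-like day 28 36, oligodendrocyte-like day 28 28, phagocyte-like day 28 38. Endothelial-like day 14 1, day 28 2, fibroblast-like day 7 19, day 28 15, the class sum day 28 147. Fewer genes passed: OPC-like any day 469, day 3 585, day 7 19, day 14 1, day 28 5, mural-like day 3 112.

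With RLE size factors more genes passed: excitatory neuron-like day 7 9, inhibitory neuron-like day 7 3. Fewer genes passed: whole cortex day 28 0 in edgeR (1966 at unadjusted p under 0.05). With TMM on class counts share calls were lost at log2: newly formed oligodendrocyte-like day 3 1.24, OPC-like day 3 0.34, day 28 against 3 -0.47, endothelial-like day 3 0.61, day 28 against 3 -0.61. As a difference from the other classes (limma) more genes passed: excitatory neuron-like day 7 7, inhibitory neuron-like day 7 1, day 14 1, astrocyte-like day 14 28, day 28 19. Phagocyte-like day 28 51, endothelial-like day 14 4, fibroblast-like day 7 19, day 28 7. Fewer genes passed: excitatory neuron-like any day 352, day 3 912, inhibitory neuron-like any day 50, day 3 349, astrocyte-like any day 619, day 3 971, day 7 126. Oligodendrocyte-like any day 233, day 3 309, day 7 53, day 14 3, OPC-like any day 200, day 3 209, day 7 6, day 14 1, day 28 0 in limma (382), phagocyte-like any day 479, day 3 750, day 7 414. Endothelial-like any day 124, day 3 167, day 7 22, mural-like any day 0 in limma (105), day 3 3, fibroblast-like any day 96, day 3 234, day 14 10. The class sum any day 2153, day 3 3904, day 7 648, day 28 against 3 2740.

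At or above the whole cortex level fewer genes passed: excitatory neuron-like any day 1105, day 3 1648, day 7 0 in edgeR (2411 of all genes at unadjusted p under 0.05), inhibitory neuron-like any day 317, day 3 841, day 28 0 in edgeR (658), OPC-like day 14 3. The class sum day 3 10316, day 28 against 3 10206. In libraries with at least 50 nuclei fewer genes passed: mural-like any day 6, day 3 44. With no filter on low counts more genes passed: inhibitory neuron-like day 7 3, astrocyte-like day 7 694, day 14 155, day 28 182, oligodendrocyte-like day 14 68, day 28 88. OPC-like day 14 20, day 28 15, phagocyte-like day 14 454, day 28 113, endothelial-like day 14 20, day 28 17. Mural-like any day 140, day 7 4, day 14 3, day 28 5, fibroblast-like any day 1303, day 7 69, day 14 176, day 28 66, the class sum day 14 896, day 28 487. Fewer genes passed: whole cortex day 28 0 in edgeR (2034).

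In nuclei with at least 1000 UMIs more genes passed: astrocyte-like day 28 24. Fewer genes passed: whole cortex day 14 0 in edgeR (1395 at unadjusted p under 0.05), day 28 0 in edgeR (1641), oligodendrocyte-like any day 856, day 3 892, OPC-like day 28 4. Endothelial-like any day 485, day 3 529, day 7 1, fibroblast-like any day 403, day 3 459, day 7 5, day 14 6. Share calls were lost at log2: OPC-like day 3 0.72, day 28 against 3 -0.55, phagocyte-like day 28 1.10, oligodendrocyte-like day 28 against 3 0.32. With a replicate block more genes passed: astrocyte-like day 28 46, oligodendrocyte-like day 28 16, phagocyte-like day 28 56. Endothelial-like day 28 4, fibroblast-like day 14 44, day 28 11, the class sum day 28 146. Fewer genes passed: whole cortex day 28 0 in edgeR (2040), inhibitory neuron-like any day 472. Share calls were lost at log2: newly formed oligodendrocyte-like day 3 1.37, OPC-like day 3 0.53. Among non-neuronal nuclei share calls were lost at log2: newly formed oligodendrocyte-like day 3 0.99, OPC-like day 3 0.076, endothelial-like day 3 0.36. Phagocyte-like day 28 0.30. Without nuclei with 3 or more markers of another class more genes passed: endothelial-like day 28 1, mural-like any day 208, day 3 256, day 7 7, day 28 6, fibroblast-like day 28 9. Fewer genes passed: inhibitory neuron-like any day 381, day 3 1101, day 28 0 in edgeR (518), astrocyte-like day 7 231, day 14 3, OPC-like any day 455, day 3 544, day 7 11, day 14 2, day 28 4. Endothelial-like day 7 31, fibroblast-like any day 419, day 3 570, day 7 2. With an estimated correlation 0 gene list tests passed in camera, in the classes and in whole cortex.

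Differences from the other classes with the opposite sign to the fold itself stood, in log2, as follows. Excitatory neuron-like day 3 Gria2 0.11, Flrt3 0.0083, Hspe1 0.060, Hspa8 0.51, Hsp90aa1 0.62, day 28 against 3 Hspa8 -0.53, Aldoa -0.65. Inhibitory neuron-like day 3 Spp1 -0.82, Ptgds 0.41, Shank3 -0.38, Hspe1 0.24, Hspa8 0.31, Hsp90aa1 0.44, Aldoa 0.29, day 28 against 3 Gria2 -0.12, Hspa8 -0.23, Aldoa -0.24. Astrocyte-like day 7 Gfap -0.33, Aqp4 -0.10, Mlc1 -0.029, day 14 Gfap -0.13, day 28 C4b -0.22, day 28 against 3 Ggta1 0.30, Aqp4 0.088. Oligodendrocyte-like day 3 Cldn11 -0.0058, Mal 0.17, Hspa8 0.11, Hsp90aa1 0.25, Hspe1 0.11, day 28 against 3 Aspa -0.38, Hspa8 -0.034, Hsp90aa1 -0.20, Hspe1 -0.17. OPC-like day 3 Mki67 -0.26, Diaph3 -0.18, Top2a -1.05, Serpina3n -0.27, day 28 Cdk8 0.035, day 28 against 3 Mki67 0.62, Tnc 0.072. Phagocyte-like day 3 Trim30a -0.026, C4b -1.02, day 7 Ddx60 -0.42, C4b -0.10, day 14 C4b -0.18, day 28 against 3 Apoe -0.18. Endothelial-like day 3 Col4a1 -0.0067, Fn1 -0.66, day 28 against 3 Fn1 0.39. Mural-like day 3 Ptgds 0.10, Col4a1 -0.11. Fibroblast-like day 3 Mki67 -0.63, Top2a -1.95, Cenpe -0.50. Fosb in excitatory neuron-like nuclei at day 3 turned without day 3 replicate 1 (-0.014, the lowest of its leave-one-out values, the highest 2.95).

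With all libraries, and in brackets lowest to highest with 1 left out, counts that moved over 1.5 times were: whole cortex day 7 1040 (405 to 1906), day 14 306 (8 to 456), day 28 3 (0 to 15), excitatory neuron-like day 7 4 (0 to 395), day 28 0 (0 to 5). Inhibitory neuron-like any day 711 (177 to 889), day 3 1790 (586 to 2284), day 7 0 (0 to 5), day 28 1 (0 to 3), astrocyte-like day 7 359 (138 to 617), day 14 16 (0 to 55), day 28 12 (0 to 69). Oligodendrocyte-like day 3 1702 (1125 to 1729), day 7 358 (92 to 477), day 14 10 (1 to 36), day 28 10 (6 to 29), OPC-like any day 791 (516 to 849), day 3 951 (629 to 1055), day 7 36 (8 to 66), day 14 5 (2 to 14), day 28 8 (3 to 16). Phagocyte-like day 7 810 (324 to 888), day 14 260 (87 to 348), day 28 25 (3 to 58), endothelial-like day 3 1435 (777 to 1507), day 7 103 (11 to 166), day 14 0 (0 to 1), day 28 0 (0 to 7). Mural-like any day 50 (6 to 83), day 3 170 (44 to 268), fibroblast-like any day 710 (295 to 799), day 3 918 (449 to 978), day 7 10 (2 to 18), day 14 25 (1 to 38), day 28 4 (1 to 10). The class sum day 7 1680 (585 to 2623), day 14 316 (101 to 450), day 28 60 (20 to 167). Other counts above started from excitatory neuron-like any day 2825, day 3 4501, astrocyte-like any day 2276, day 3 2689, oligodendrocyte-like any day 1400, phagocyte-like any day 2043, day 3 2059. Endothelial-like any day 1166, the class sum any day 11972, day 3 16215, day 28 against 3 15932. Leaving out 1 ended calls of these share folds, in log2: newly formed oligodendrocyte-like day 3 0.58 to 1.82, day 7 1.18 to 1.99, day 28 against 3 -1.91 to -0.73, OPC-like day 3 0.31 to 0.68, day 28 against 3 -0.78 to -0.41, lymphocyte-like day 3 2.02 to 4.26. Endothelial-like day 3 0.67 to 1.05, day 28 against 3 -0.92 to -0.67, fibroblast-like day 14 0.96 to 1.69, phagocyte-like day 28 0.49 to 0.78. Oligodendrocyte-like day 28 against 3 0.60 to 0.74. Any-day counts moved in inhibitory neuron-like nuclei without sham replicate 2 (399) or 3 (426) or day 3 replicate 1 (177), in OPC-like without day 3 replicate 1 (516), in mural-like without day 3 replicate 1, 2 or 3 (6, 10 and 83) and in fibroblast-like without day 3 replicate 2 (295).

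The replicate number was taken as only a shared number, since in no compared pair of groups did every same-numbered pair correlate over 0.1. Across groups the median correlation of residuals was 0.0211 for the same number and -0.00980 for different ones. Not every library correlated best with 1 of its own number. The 3 same-numbered pairs of days 7 and 14, which were not compared with each other, all stood over 0.1 (0.159, 0.1002 and 0.122), as did day 3 replicate 3 with replicate 3 of these days (0.165 and 0.285), so a link is not excluded.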

Other observations

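These genes were chosen after their values were seen, so no p-value below is an independent test. Cdk8 fell past the threshold in edgeR in 4, 4, 0 and 5 of 9 classes at days 3, 7, 14 and 28. At day 14 it stood near sham in whole cortex (391 against 382 CPM, log2 0.036). The classes share libraries, so their agreement is not independent. At day 28 the log2 fold was -0.87 ± 0.13 in oligodendrocyte-like (adjusted p = 0.000725), -0.85 ± 0.14 in phagocyte-like and -0.76 ± 0.14 in astrocyte-like nuclei. Cmss1, a gene of ribosome assembly, fell past it in 0, 2, 0 and 4 classes. At day 3 it rose in whole cortex (log2 0.53, adjusted p = 0.00601), excitatory neuron-like and astrocyte-like nuclei. At day 28 its log2 fold was -0.81 ± 0.11 in OPC-like and -0.64 ± 0.12 in oligodendrocyte-like nuclei. Of 4 genes of the circadian clock, Dbp stood below sham in 7 of 7 classes at each day and fell past the threshold in 4, 0, 1 and 0. Arntl stood above in 4, 6, 6 and 7 of 7 classes. Nr1d2 stood below in 8, 7, 9 and 8 of 9 (past the threshold in 3, 0, 0 and 0) and Per1 in 4, 4, 5 and 4 of 6 (0, 0, 0 and 1).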
